A study of Oryza sativa with 18 samples.

How the data were processed

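RNA from laser-microdissected outer cells of rice roots was hybridized by the authors to 18 dual-colour 44K Agilent arrays, each with stagnant long RNA in 1 dye. Per the file headers, the scanner files were made with Agilent Feature Extraction 9.5.3.1. The deposited scanner files give the mean intensity of each spot and the median intensity of its background in both dyes. The deposited ratio column and the deposited series table give the log10 of Cy5 over Cy3 after the software's own background and dye correction. Each array has 45151 spots, of which 43734 are not controls and 42105 carry a locus name, for 29689 loci, 21893 of them with 1 probe.

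Intensities were read in R 4.3.3 with data.table (version 1.17.8) and corrected in limma 3.58.1 by normexp with an offset of 50, then by loess within arrays with control spots at weight 0. Spots the software marked as outliers, at most 84 per array, were left out, and 1 spot was saturated. Ratios were turned to stagnant long over the other RNA and the 2 arrays of a dye swap were averaged to 1 replicate. The brightest probe stood for a locus. A locus was tested where its probe was well above background in either dye on at least 4 of 6 arrays of a comparison, which left 16094 loci, 26 of them without a ratio in some replicate. The 9 ratios were fitted in limma with a coefficient per comparison and eBayes with a trend. P values were adjusted by Benjamini and Hochberg over all loci, with a threshold of 0.05. N2-flushed and stagnant short roots were set against aerated roots as differences of coefficients. A locus was called changed in all 3 comparisons from the largest of its 3 p values where the signs were equal. Where 1 of the RNAs was well above background on 0 of 6 arrays, the fold in a direct comparison was given as a lower bound, and none in an indirect comparison. The bound came from mean channel levels after loess and Aquantile. On each array the dim level was set to its own signal or to the lowest signal well above background, whichever was higher. The bound holds for the mean over replicates and does not allow for their spread.

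Gene lists were made from the array's descriptions. There were 25 lists fixed beforehand, on suberin, phenylpropanoids, laccases, peroxidases, fermentation, glycolysis, ethylene, transcription factors, transporters, lipids, walls, nitrogen, heat shock, cell division, ribosomes and other tissues. Another 10 lists were chosen after seeing the data: chitinases, germin-like proteins, metallothioneins, iron acquisition, proteinase inhibitors, lipases and hydrolases, glutathione S-transferases, organellar ribosomal proteins, proteasome, and tubulin and actin. Lists with at least 3 members were tested with camera at a preset correlation of 0.01, with an estimated correlation (statmod 1.5.0 was used for block correlations), and with fry. Of 69 tests on fixed lists, 12 were past the threshold with the preset, 1 with an estimated correlation, glycolysis against stagnant short roots, and 27 by fry. Fry tests whether a list moves, not whether it moves more than other genes. P rose with an estimated correlation even where the estimate lay below the preset, as for suberin. Such a loss therefore need not mean correlated members.

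Named genes followed a rule. In each direct comparison it took the 8 highest and 8 lowest ratios past the test with the same sign in all 3 replicates and a described function. It took up to 4 members per list by lowest p, and loci given by name whatever their p. It took 12 higher and 6 lower loci changed in all 3 comparisons, and 5 per direction in each indirect comparison. The text gives part of the genes the rule takes, and that part was chosen after their values were seen. Samples were paired by the replicate numbers per the labels. Deviations of same-numbered ratios from their group mean correlated between 0.139 and 0.654 over 9 pairs, and those of other numbers between -0.514 and 0.101 over 18 pairs. Deviations within a group cancel out, so positive values for the same number push those of other numbers negative on average. The ranges are therefore not separate evidence. Same-numbered arrays share slides, and whether they share 1 extract of stagnant long RNA is not stated. The replicate correlation was 0.221 by duplicateCorrelation.

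The fit, but not background correction, loess, the filter or the choice of probe, was tested on simulated ratios. Their noise was normal, with each locus's fitted spread and the replicate correlation of 0.221. There 98, 97 and 98 of 100 loci changed 2-fold were recovered in the 3 direct comparisons. Of the calls, 4 of 201, 7 of 116 and 8 of 106 were on unchanged loci. These shares need not hold for the real ratios. Groups, comparisons, fixed lists, the rule for named genes and the alternatives were chosen before the data were examined. The alternatives were other background correction, other normalization, the scanner software's ratios, the series table, other filters, the mean over probes, other variance models, separate fits, dye coefficients, replicate blocks, separate channels, and each replicate left out. Where a group was left with 2 replicates, limma pooled the spread over groups. Of called loci with another probe, 42 of 1156, 43 of 1358 and 36 of 909 had a probe of opposite sign in the 3 direct comparisons. No locus name was found among the 39387 entries of the reference table, so coordinates and symbols were left out. Spots without a locus name were left out of the comparisons.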

Results

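Gene expression was measured in the outer cells of adventitious roots of rice (Oryza sativa, cultivar Nipponbare), which per the labels comprise the exodermis and the sclerenchyma. Laser microdissection took these cells from the root base, between 12.5 mm and 22.5 mm from the shoot. Plants aged 23 days were kept for 9 h in aerated solution, in solution flushed with N2 gas, or in a stagnant deoxygenated solution thickened with 0.1% agar. Both low-oxygen solutions held less than 1 mg of oxygen per litre. Long roots measured 115 to 135 mm and short roots 65 to 85 mm when the treatments began. Each of the 18 arrays set RNA of stagnant long roots beside RNA of aerated long, N2-flushed long or stagnant short roots. Every comparison had 3 replicates, and each replicate had 2 arrays with opposite dyes. The labels place the study in the forming of a barrier to radial oxygen loss, a seal of the outer root that slows the escape of oxygen.

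Between 24.1% and 60.9% of the gene spots of a channel were well above background, with a median of 48.7%. The median was 51.3% over 18 channels of stagnant long RNA, and over 6 channels each it was 41.9% for aerated long, 47.5% for N2-flushed long and 42.6% for stagnant short RNA. Of the 29689 loci on the array, 16094 were tested, and the number of arrays limits the precision. Ratios are given on the log2 scale as stagnant long over the other RNA, ± the standard error of the limma fit over n = 3 replicates. A positive ratio is a higher level in stagnant long roots. Genes carry the array's own descriptions and locus names, and the files gave no coordinates or genome build. With median centring in place of loess the median of all loci moved to 0.29 against aerated long, 0.04 against N2-flushed long and 0.20 against stagnant short. The scanner software's own ratios had medians of 0.13, 0.01 and 0.11. Lists whose median turned its sign under a scaling are named in each direct comparison. Values named below as past the test in the 3 direct comparisons had the same sign in all 3 replicates.

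The comparison with aerated long roots asks what the stagnant solution changed in the outer cells of long roots. Haemoglobin 1 (Os03g0233900), which scavenges nitric oxide in oxygen-poor cells, stood at 2.70 ± 0.38 (adjusted p = 0.00165). Alcohol dehydrogenase 1 (Os11g0210300) and alcohol dehydrogenase 2 (Os11g0210500), which end ethanol fermentation, stood at 1.24 ± 0.15 and 1.06 ± 0.14, and pyruvate decarboxylase 2 (Os03g0293500), the step before them, at 0.95 ± 0.10. Nitrate reductases Os02g0770800 and Os08g0468100, which start nitrate assimilation, were higher by 1.59 ± 0.18 and 1.00 ± 0.12. Asparagine synthetase (Os03g0291500), which stores nitrogen as asparagine, was lower at -3.01 ± 0.27 (adjusted p = 0.000211). With scale normalization the decarboxylase and the synthetase were not past the test, with adjusted p = 0.0711 and 0.0794.

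Pathogenesis-related protein 1 (Os07g0129300) at 3.63 ± 0.69 (adjusted p = 0.00676) and BCH2 (Os02g0112100) at 3.36 ± 0.30 were past the test, but their aerated signals were well above background on 3 and 2 of 6 arrays, so the sizes of these ratios are uncertain. The former lost its call with scale normalization (adjusted p = 0.0979) and without replicate 2 (adjusted p = 0.107). Other high ratios were those of metallothionein Os12g0571000, a small metal-binding protein, at 2.86 ± 0.16, membrane transporter Os02g0112600 at 2.80 ± 0.27, GDSL lipase Os01g0216000 at 2.42 ± 0.38, lipid-transfer-domain protein Os10g0552600 at 2.38 ± 0.46 and cationic peroxidase Os07g0677600 at 2.32 ± 0.41. The lipase lost its call with scale normalization (adjusted p = 0.194). The lipid-transfer-domain protein and the peroxidase lost theirs without replicate 2 (adjusted p = 0.0987 and 0.0528), and the former also without aerated long replicate 2 or 3 (adjusted p = 0.0541 or 0.0575). CTP synthase (Os01g0654100), which makes a nucleotide for RNA and lipid synthesis, was lower at -3.17 ± 0.16 (adjusted p = 1.60e-05). Other low ratios, besides that of asparagine synthetase, were those of the CI2C gene Os12g0548700 at -2.84 ± 0.16 and chitinase Os10g0542900, an enzyme that attacks fungal walls, at -2.83 ± 0.16. Proline dehydrogenase Os10g0550900, which breaks down proline, stood at -2.72 ± 0.11, and myo-inositol oxygenase Os06g0561000, which leads to wall sugars, at -2.70 ± 0.13. F-box protein Os02g0671100 was at -2.60 ± 0.26 and germin-like protein 6 (Os08g0189600) at -2.54 ± 0.24, which became -1.45 with adjusted p = 0.0501 under median centring.

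The suberin list, whose genes build the waxy polyester of root barriers, had 3 of 13 members higher and 0 lower (6 and 0 adjusted over the list alone). Fatty acyl-CoA reductase Os08g0557800, which makes the fatty alcohols of suberin, was higher at 1.15 ± 0.20, as were condensing enzyme CUT1 (Os03g0220100) at 0.66 ± 0.15 and CYP86A1 (Os03g0140200), a fatty acid hydroxylase, at 0.59 ± 0.12. CUT1 was not past the test with the scanner software's ratios (adjusted p = 0.0612), the series table (0.0608), scale normalization (0.0689) or on own replicates (0.0652). It was not without replicate 2 or 3 (0.0881 or 0.0934), nor without aerated long replicate 2 or 3 (0.0995 or 0.0729). CYP86A1 lost its call without replicate 2 or 3 (0.0987 or 0.0697) and without aerated long replicate 2 (0.0575), and the reductase with scale normalization (0.169) and without replicate 2 (0.0776). CYP86B1-like P450 Os10g0486100 at 1.20 ± 0.39 (adjusted p = 0.0612) and ABC transporter Os03g0281900 at 1.12 ± 0.36 (adjusted p = 0.0591) were not past the test. The suberin list had a median of 0.59 and was not called, with adjusted p = 0.19. The median became 1.30 under median centring, with adjusted p = 0.052. Plastid fatty acid synthesis had 8 of 21 members higher and 0 lower (9 and 1 adjusted over the list alone), and the list was called higher, with adjusted p = 0.0034 and adjusted p = 0.425 with an estimated correlation. Its members included acetyl-CoA carboxylase Os10g0363300 at 0.38 ± 0.06, which is described as cytosolic and so lies outside the plastid pathway of the list's name, and acyl-ACP desaturase Os01g0880800, whose aerated signal was well above background on 0 of 6 arrays and whose mean level was at least 2.33-fold higher in stagnant roots. The call of the desaturase was lost without replicate 2 (adjusted p = 0.0709) and without aerated long replicate 3, where its log2 ratio was 0.95 (adjusted p = 0.0747). The carboxylase lost its call with scale normalization (adjusted p = 0.109) and without replicate 2 (adjusted p = 0.0778). Lipid transfer proteins had 2 of 9 members higher and 1 lower (2 and 1 adjusted over the list alone), among them Os07g0174900 at 1.72 ± 0.41. It was not past the test with the scanner software's ratios (adjusted p = 0.0866), the series table (0.0865) or scale normalization (0.402), nor without replicate 2 (0.179) or aerated long replicate 2 or 3 (0.107 or 0.0833). Phenylpropanoid genes, which feed lignin and the phenolic part of suberin, had 1 of 36 members higher and 8 lower (1 and 8 adjusted over the list alone), and 4-coumarate-CoA ligase-like Os04g0683700 was at -1.34 ± 0.20, but at -0.19 with adjusted p = 0.768 under median centring. Phenylalanine ammonia-lyase Os02g0627100 was lower at -0.89 ± 0.21, but stood at 0.14 with adjusted p = 0.837 under median centring. It lost its call with scale normalization (adjusted p = 0.0596), without replicate 2 or 3 (0.0522 or 0.118) and without aerated long replicate 1, 2 or 3 (0.068, 0.0589 or 0.0848). The ligase lost its call with scale normalization (0.202) and without replicate 2 (0.0529). The list held also cinnamyl alcohol dehydrogenase Os02g0187800, not past the test at -0.43 ± 0.19.

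The fermentation list had 9 of 24 members higher and 5 lower (9 and 5 adjusted over the list alone), with sucrose synthase 2 (Os03g0401300) not past the test at -0.27 ± 0.43. Glycolysis, the breakdown of sugar to pyruvate, had 9 of 48 members higher and 3 lower (9 and 4 adjusted over the list alone), with the pyrophosphate-dependent phosphofructokinase Os06g0247500 at 0.68 ± 0.10 and enolase Os10g0167300 at -0.80 ± 0.14, which became 0.35 with adjusted p = 0.579 under median centring. The enolase was not past the test with scale normalization (adjusted p = 0.190) or without replicate 2 (0.0905), nor was the phosphofructokinase without replicate 2 (0.052). Nitrogen uptake and assimilation had 8 of 34 members higher and 5 lower (8 and 8 adjusted over the list alone), and nitrate transporter Os10g0554200 stood at 1.04 ± 0.17. Genes of ethylene, the gas hormone of flooded roots, had 3 of 19 members higher and 2 lower (3 and 2 adjusted over the list alone). Ethylene receptor Os04g0169100 was higher at 0.93 ± 0.06, and ACC oxidases Os11g0186900 and Os05g0149400, which make the hormone, were lower at -1.68 ± 0.19 and -1.22 ± 0.17, the latter at -0.61 with adjusted p = 0.120 under median centring. WRKY transcription factors had 5 of 45 members higher and 17 lower (5 and 22 adjusted over the list alone) and a median of -0.16, which became 0.19 under median centring. The list was called lower, with adjusted p = 0.000733 and adjusted p = 0.268 with an estimated correlation. WRKY69 (Os08g0386200) was at -1.49 ± 0.16, or -0.79 with adjusted p = 0.0808 under median centring, against 1.07 ± 0.14 for WRKY gene Os01g0734000. MYB factors had 10 of 94 members higher and 11 lower (18 and 14 adjusted over the list alone), led by Os03g0764600 at -2.23 ± 0.16. AP2/ERF factors had 5 of 29 members higher and 5 lower (5 and 8 adjusted over the list alone), including Os06g0194000 at 0.92 ± 0.08 and Os02g0654700 at -1.54 ± 0.15. NAC factors had 2 of 32 members higher and 9 lower (4 and 10 adjusted over the list alone), including Os01g0261200 at -0.63 ± 0.08, which became 0.27 with adjusted p = 0.636 under median centring. Under that scaling the medians of the NAC and phenylpropanoid lists turned from -0.09 to 0.27 and from -0.04 to 0.45, and that of AP2/ERF factors, near 0, to 0.47. Other medians that turned were those of phenylpropanoid genes with offset 0, of AP2/ERF factors with offset 0, with the scanner software's ratios, with the series table and without background subtraction, and of fermentation genes and ABCG transporters without background subtraction.

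Secondary wall genes had 5 of 15 members higher and 1 lower (5 and 1 adjusted over the list alone), where those higher included fasciclin-domain proteins Os01g0668100 at 1.72 ± 0.25 and Os05g0563600 at 1.75 ± 0.40. The latter lost its call with scale normalization (adjusted p = 0.0882), on own replicates (0.0794), without replicate 1 or 2 (0.119 or 0.142) and without aerated long replicate 1 or 2 (0.0685 or 0.0940). Class III peroxidases had 5 of 49 members higher and 9 lower (5 and 10 adjusted over the list alone). Laccases had 1 of 5 members higher and 0 lower (1 and 0 adjusted over the list alone), and ABCG transporters 0 of 5 members higher and 1 lower (1 and 1 adjusted over the list alone). Expansins and xyloglucan endotransglucosylases had 2 of 14 members higher and 2 lower (4 and 2 adjusted over the list alone), and aquaporins 1 of 8 members higher and 1 lower (1 and 1 adjusted over the list alone). The sole wall-associated kinase measured, Os04g0365100, was lower at -0.42 ± 0.10. It stood at -0.04 with adjusted p = 0.879 under median centring, and its adjusted p was 0.177 or 0.0672 without replicate 2 or 3, and 0.0937 or 0.103 without aerated long replicate 2 or 3. Cell division genes had 10 of 87 members higher and 4 lower (9 and 4 adjusted over the list alone) and heat shock proteins 9 of 92 members higher and 10 lower (9 and 11 adjusted over the list alone). Cytosolic ribosomal proteins had 11 of 228 members higher and 0 lower (0 and 0 adjusted over the list alone), with a median of 0.08. The list was called higher, with adjusted p = 0.000733 and adjusted p = 0.657 with an estimated correlation. Without replicate 2, or without aerated long replicate 2, the adjusted p was 0.136 or 0.116. Markers of other tissues stood beside these groups as follows: stele and vascular genes had 0 of 5 members higher and 1 lower (0 and 1 adjusted over the list alone), cortex genes 0 of 2 members higher and 0 lower (0 and 0 adjusted over the list alone), and green tissue genes 2 of 30 members higher and 5 lower (3 and 6 adjusted over the list alone). The green tissue median turned from -0.02 to 0.22 under median centring. Median, mean and test differed in sign for peroxidases, ABCG transporters, heat shock proteins and stele genes, and no such list was called.

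In limma, 3106 of 16094 loci passed an adjusted p of 0.05 against aerated long roots, 1496 higher and 1610 lower, and 353 of them differed at least 2-fold. Median centring gave 3557 loci, 1698 of them among the 3106, with 83.0% higher in place of 48.2%, and 855 at least 2-fold. The count was 1755 with scale normalization between arrays and 1522 on the comparison's own replicates, 555 or 1517 without replicate 2 or 3 of every comparison, and 1401 or 1584 without aerated long replicate 2 or 3 alone. Of the genes named against aerated roots as past the test, these numbers lost their call (adjusted p in parentheses): 2 with the scanner software's ratios (0.0612 to 0.0866), 2 on own replicates (0.0652 to 0.0794), 5 with median centring (0.0501 to 0.879) besides the 3 whose sign turned, 12 with scale normalization (0.0596 to 0.402), 2 with the series table (0.0608 to 0.0865), 2 without aerated long replicate 1 (0.068 to 0.0685), 7 without aerated long replicate 2 (0.0541 to 0.107), 6 without aerated long replicate 3 (0.0575 to 0.103), 1 without replicate 1 (0.119), 15 without replicate 2 (0.052 to 0.179) and 4 without replicate 3 (0.0672 to 0.118).

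**Figure D1:**
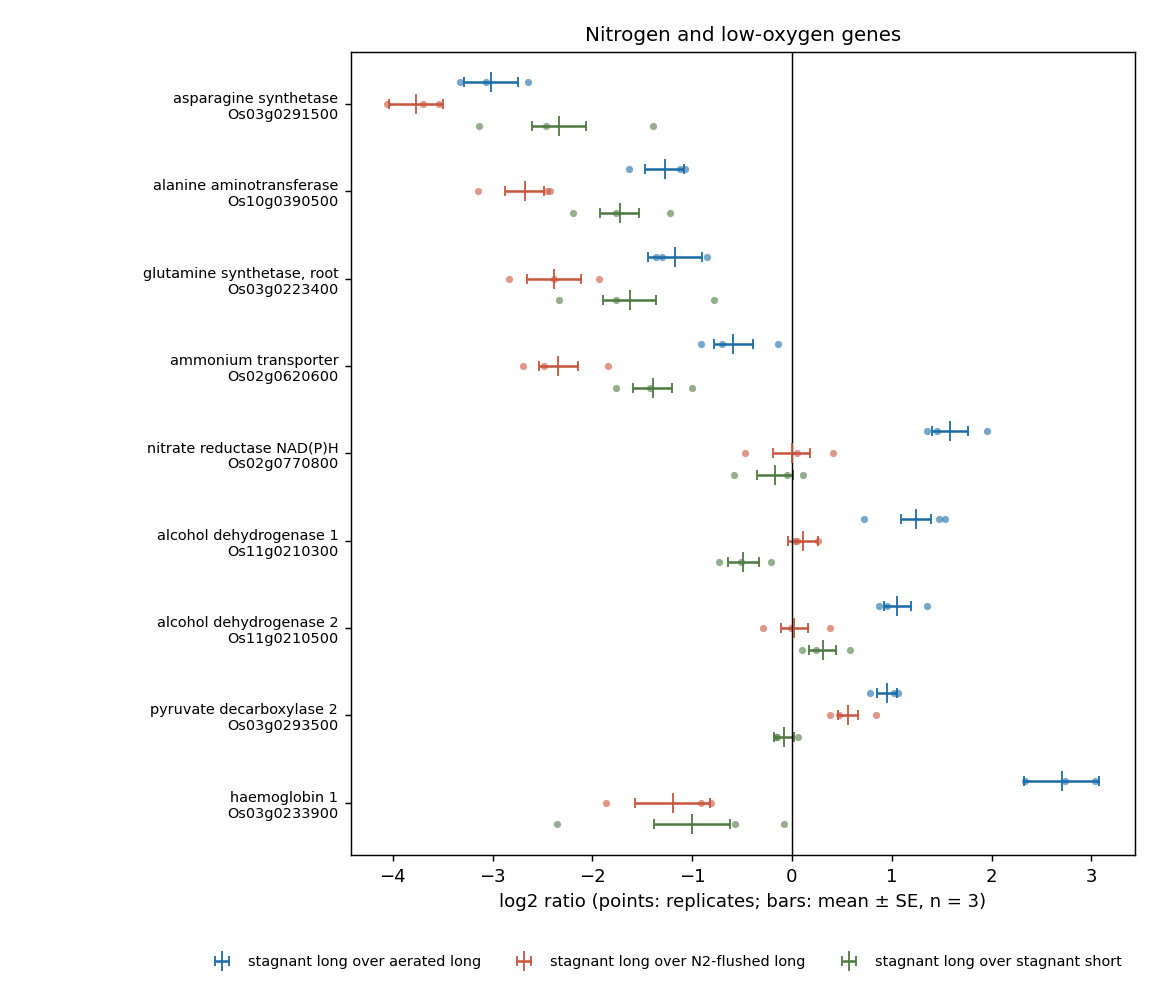
Log2 ratios (x axis) of 9 genes of nitrogen and low-oxygen metabolism (y axis), with points for the 3 replicates and bars for the mean ± standard error, in 1 colour per comparison. The standard error is that of the fit, pooled over all 9 ratios. Asparagine synthetase lay below 0 in all 3 comparisons, from -3.01 against aerated to -3.77 against N2-flushed and -2.33 against stagnant short roots, while haemoglobin 1 reached 2.70 against aerated roots.

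The comparison with N2-flushed long roots sets a stagnant against a flushed low-oxygen solution in roots of like length. Lipid transfer protein Os07g0174900 stood at 3.70 ± 0.41 (adjusted p = 0.000368), CYP86B1-like P450 Os10g0486100, of a family that hydroxylates very long fatty acids, at 2.72 ± 0.39 (adjusted p = 0.0013), and beta-ketoacyl reductase Os04g0483500, a step of fatty acid elongation, at 2.72 ± 0.46. Without replicate 2 the P450 and the reductase were not past the test, with adjusted p = 0.0511 and 0.0814. Cytosolic ribosomal protein genes had 170 of 228 members higher. Lower were asparagine synthetase (Os03g0291500) at -3.77 ± 0.27 (adjusted p = 5.38e-05), root glutamine synthetase (Os03g0223400) at -2.39 ± 0.27 and ammonium transporter Os02g0620600 at -2.34 ± 0.20.

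Other high ratios were those of PspC gene Os07g0599700 at 3.44 ± 0.28, peroxidase 11 (Os06g0274800) at 3.02 ± 0.37, BCH2 (Os02g0112100) at 2.67 ± 0.30, ABC transporter Os03g0281900 at 2.54 ± 0.36 and hydrolase Os02g0706900 at 2.53 ± 0.33. Among the lowest were the wound-induced proteinase inhibitor WIP1 (Os01g0132000) at -3.31 ± 0.31, hydrolase Os01g0595600 at -3.12 ± 0.18, haem peroxidase Os05g0135500 at -3.09 ± 0.42 and family 18 glycoside hydrolase Os05g0247100 at -3.01 ± 0.21. Protein kinases Os12g0113500 and Os11g0113700 stood at -2.96 ± 0.26 and -2.89 ± 0.19, and aldolase C-1 (Os08g0120600), a glycolytic enzyme, at -2.70 ± 0.16.

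The suberin list had 5 of 13 members higher and 1 lower (5 and 1 adjusted over the list alone). Fatty acyl-CoA reductase Os08g0557800 at 1.46 ± 0.20 and CUT1 (Os03g0220100) at 1.13 ± 0.15 were higher, and CYP86A1 (Os03g0140200) was lower at -1.03 ± 0.12, but at -0.94 with adjusted p = 0.236 under median centring. The list had a median of 0.37 and was not called, with adjusted p = 0.116. Plastid fatty acid synthesis had 10 of 21 members higher and 0 lower (10 and 0 adjusted over the list alone), including the acetyl-CoA carboxylase described as cytosolic (Os10g0363300) at 0.58 ± 0.06 and acyl carrier protein III (Os09g0539800) at 0.83 ± 0.11, which stood at 0.67 and 0.91 with adjusted p = 0.426 and 0.188 under median centring. That list was called higher, with adjusted p = 0.0391 and adjusted p = 0.385 with an estimated correlation. Without N2-flushed long replicate 3 the adjusted p was 0.067. Lipid transfer proteins had 2 of 9 members higher and 1 lower (2 and 1 adjusted over the list alone), and phenylpropanoid genes had 14 of 36 members higher and 5 lower (17 and 5 adjusted over the list alone), with cinnamoyl-CoA reductase Os09g0419200, which opens the lignin branch, at 1.15 ± 0.18 and Os04g0683700 at -2.28 ± 0.20. The reductase lost its call without replicate 2 (adjusted p = 0.0656). Phenylalanine ammonia-lyase Os02g0627100 was not past the test at 0.39 ± 0.21, nor was cinnamyl alcohol dehydrogenase Os02g0187800 at -0.00 ± 0.19.

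Fermentation genes had 2 of 24 members higher and 6 lower (2 and 10 adjusted over the list alone). Alanine aminotransferase Os10g0390500, which turns pyruvate to alanine, was lower at -2.68 ± 0.20 (adjusted p = 5.67e-05), as was sucrose synthase 2 (Os03g0401300) at -2.18 ± 0.43, while alcohol dehydrogenases 1 (Os11g0210300) and 2 (Os11g0210500) were not past the test at 0.11 ± 0.15 and 0.02 ± 0.14. The synthase lost its call without replicate 1 (adjusted p = 0.07) and without N2-flushed long replicate 3 (adjusted p = 0.0581). Glycolysis had 4 of 48 members higher and 15 lower (5 and 16 adjusted over the list alone), with the pyrophosphate-dependent phosphofructokinases Os05g0194900 and Os01g0191700, which spare ATP, at -1.71 ± 0.12 and -1.72 ± 0.16. Nitrogen uptake and assimilation had 2 of 34 members higher and 9 lower (2 and 10 adjusted over the list alone), and NADH glutamate synthase (Os01g0681900) stood at -1.86 ± 0.13. Under median centring the medians of glycolysis and of nitrogen genes turned from -0.04 to 0.02 and from -0.04 to 0.01. Cytosolic ribosomal proteins had 170 of 228 members higher and 1 lower (182 and 2 adjusted over the list alone), for example 60S protein L38 (Os11g0433900) at 1.29 ± 0.06 and 40S protein S23 (Os01g0834500) at 0.99 ± 0.07, which stood at 1.38 and 1.08 with adjusted p = 0.100 and 0.203 under median centring. Their median was 0.53, and the list was called higher, with adjusted p = 5.26e-47 and adjusted p = 0.357 with an estimated correlation.

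Ethylene genes had 7 of 19 members higher and 3 lower (11 and 4 adjusted over the list alone), with receptors Os04g0169100 at 1.12 ± 0.06 and Os02g0820900 at 0.67 ± 0.07 higher and ACC synthase Os01g0192900 lower at -1.0 ± 0.14. Under median centring the receptors stood at 1.21 and 0.76 with adjusted p = 0.0633 and 0.148, and the ACC synthase lost its call without replicate 2 (adjusted p = 0.0508). AP2/ERF factors had 2 of 29 members higher and 7 lower (2 and 7 adjusted over the list alone) and MYB factors 12 of 94 members higher and 7 lower (12 and 7 adjusted over the list alone). NAC factors had 6 of 32 members higher and 3 lower (6 and 3 adjusted over the list alone) and WRKY factors 4 of 45 members higher and 11 lower (4 and 12 adjusted over the list alone). The MYB genes Os06g0112700 and Os03g0764600 stood at 1.70 ± 0.28 and -2.14 ± 0.16, the former with adjusted p = 0.0867 without replicate 2. Class III peroxidases had 10 of 49 members higher and 9 lower (11 and 9 adjusted over the list alone), with anionic peroxidase Os04g0688100 at 2.23 ± 0.17, and laccases had 1 of 5 members higher and 0 lower (2 and 1 adjusted over the list alone), with Os01g0827300 at 1.31 ± 0.18. ABCG transporters had 1 of 5 members higher and 0 lower (1 and 1 adjusted over the list alone), and expansins and xyloglucan endotransglucosylases 0 of 14 members higher and 2 lower (0 and 2 adjusted over the list alone). Aquaporins had 0 of 8 members higher and 1 lower (0 and 1 adjusted over the list alone), and the wall-associated kinase Os04g0365100 was not past the test at 0.09 ± 0.10. Secondary wall genes had 0 of 15 members higher and 4 lower (1 and 6 adjusted over the list alone), while cellulose synthases Os10g0467800 and Os01g0750300, of the type that builds secondary walls, were not past the test at -2.25 ± 0.74 and -1.47 ± 0.54. Heat shock proteins had 5 of 92 members higher and 14 lower (5 and 14 adjusted over the list alone), including Os02g0758000 at -1.85 ± 0.18, and cell division genes had 7 of 87 members higher and 5 lower (3 and 3 adjusted over the list alone). Beside these groups, stele and vascular markers had 0 of 5 members higher and 1 lower (0 and 1 adjusted over the list alone), cortex markers 0 of 2 members higher and 0 lower (0 and 0 adjusted over the list alone) and green tissue markers 6 of 30 members higher and 5 lower (7 and 5 adjusted over the list alone). The medians of laccases, WRKY factors, heat shock proteins and cell division genes also turned their sign under at least 1 scaling. Median, mean and test differed in sign for laccases, expansins, stele genes and green tissue genes, and no such list was called.

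Against N2-flushed long roots, 3508 loci passed the limma test, 1657 higher and 1851 lower, and 342 of them differed at least 2-fold. Median centring gave 887 loci, 44.3% of them higher in place of 47.2%, with 912 or 1734 without replicate 2 or 3 of every comparison and 1622 or 1759 without N2-flushed long replicate 2 or 3 alone. Among genes named against N2-flushed roots, the calls lost (adjusted p in parentheses) were 7 with median centring (0.0633 to 0.426), 1 without N2-flushed long replicate 3 (0.0581), 1 without replicate 1 (0.07) and 5 without replicate 2 (0.0508 to 0.0867).

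**Figure D2:**
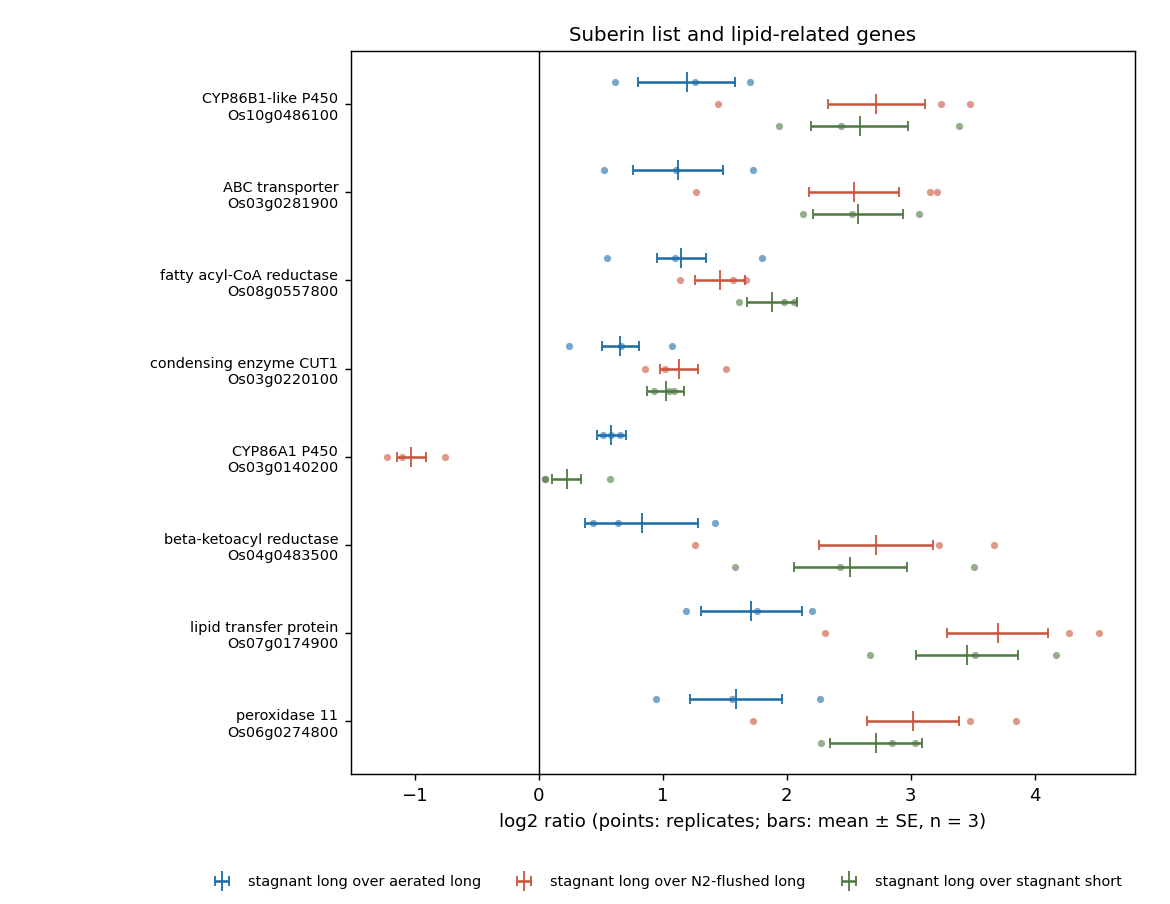
Log2 ratios (x axis) of 8 genes of the suberin list and of lipid or wall chemistry (y axis), with points for the 3 replicates and bars for the mean ± standard error, in 1 colour per comparison. The standard error is that of the fit, pooled over all 9 ratios. CYP86B1-like P450 lay at 1.20, 2.72 and 2.59 against aerated, N2-flushed and stagnant short roots, while CYP86A1 lay at -1.03 against N2-flushed roots.

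The comparison with stagnant short roots asks what root length changed at the same position from the shoot in the same solution. At that position the segment of a long root lies farther from the tip. Length therefore cannot be told apart from distance to the tip or age of the tissue. Higher in long roots were lipid transfer protein Os07g0174900 at 3.45 ± 0.41 (adjusted p = 0.00148), CYP86B1-like P450 Os10g0486100 at 2.59 ± 0.39 (adjusted p = 0.00379) and ABC transporter Os03g0281900 at 2.57 ± 0.36 (adjusted p = 0.00285). Genes of the cellulose-rich secondary wall included cellulose synthase Os10g0467800 at -2.99 ± 0.74 (adjusted p = 0.0303) among those lower, beside laccase Os11g0708100, an enzyme that joins lignin units, at -2.74 ± 0.62. Neither was past the test with offset 0, with adjusted p = 0.0566 and 0.0567, or with the scanner software's ratios, with adjusted p = 0.0913 and 0.0963, and robust eBayes gave the cellulose synthase 0.057. Without replicate 1 or 2 adjusted p was 0.148 or 0.0817 for the synthase and 0.0926 or 0.0995 for the laccase, and without stagnant short replicate 2 or 3 it was 0.0841 or 0.177 and 0.0758 or 0.135. The series table gave 0.0913 and 0.0961, and the synthase had 0.0756 without stagnant short replicate 1. With scale normalization the lipid transfer protein, the P450, the ABC transporter and the synthase were not past the test, with adjusted p = 0.0817, 0.121, 0.09 and 0.0657, nor was the P450 without replicate 2 (0.0586). Of the 48 glycolysis genes 17 were lower and 1 higher, though the list's median turned from -0.16 to 0.12 under median centring.

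Metallothionein Os12g0571000 stood at 2.96 ± 0.16, transferase Os11g0507200 at 2.87 ± 0.45, peroxidase 11 (Os06g0274800) at 2.72 ± 0.37, hydrolase Os02g0706900 at 2.57 ± 0.33 and beta-ketoacyl reductase Os04g0483500 at 2.51 ± 0.46. Lower in long roots were haem peroxidase Os05g0135500 at -2.67 ± 0.42, DNA glycosidase-like Os08g0489300 at -2.56 ± 0.44, the CI2C gene Os12g0548700 at -2.34 ± 0.16, asparagine synthetase (Os03g0291500) at -2.33 ± 0.27 and desiccation-associated protein Os11g0167800 at -2.13 ± 0.26. Nicotianamine synthase 1 (Os03g0307200), which makes a carrier of iron, was lower at -2.19 ± 0.29 (adjusted p = 0.00203). Under median centring asparagine synthetase, nicotianamine synthase and Os11g0167800 stood at -1.62, -1.34 and -1.27, with adjusted p = 0.0797, 0.15 and 0.0954. With scale normalization the metallothionein and the CI2C gene of these 11 genes were past the test and the others were not, with adjusted p between 0.0555 and 0.156. Without replicate 1 or 2 Os04g0483500 and Os08g0489300 lost their calls, as did Os05g0135500 without replicate 1 and Os11g0507200 without replicate 2, with adjusted p between 0.0565 and 0.0948.

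The suberin list had 4 of 13 members higher and 0 lower (6 and 0 adjusted over the list alone), with fatty acyl-CoA reductase Os08g0557800 at 1.88 ± 0.20 and CUT1 (Os03g0220100) at 1.02 ± 0.15, and CYP86A1 (Os03g0140200) not past the test at 0.23 ± 0.12. The list had a median of 0.27 and was called higher, with adjusted p = 0.00135 and adjusted p = 0.104 with an estimated correlation. That estimate was 0.0044, below the preset of 0.01, so correlation among members does not account for the higher p. The median became 0.77 under median centring. Plastid fatty acid synthesis had 3 of 21 members higher and 1 lower (5 and 1 adjusted over the list alone), with the acetyl-CoA carboxylase described as cytosolic (Os10g0363300) at 0.73 ± 0.06. It was called higher, with adjusted p = 0.0388 and adjusted p = 0.369 with an estimated correlation. The adjusted p was 0.101 without replicate 1, 0.059 without replicate 3, 0.0526 without aerated long replicate 1, and 0.0859 or 0.0843 without stagnant short replicate 1 or 3. Lipid transfer proteins had 2 of 9 members higher and 0 lower (2 and 0 adjusted over the list alone), including Os03g0794000 at 0.93 ± 0.16, whose adjusted p was 0.0605 without replicate 3. Phenylpropanoid genes had 5 of 36 members higher and 0 lower (5 and 0 adjusted over the list alone), including hydroxyanthranilate hydroxycinnamoyltransferase Os04g0500700 at 0.75 ± 0.08, or 1.42 with adjusted p = 0.126 under median centring, and phenylalanine ammonia-lyase Os02g0627100 and cinnamyl alcohol dehydrogenase Os02g0187800 were not past the test at 0.44 ± 0.21 and -0.37 ± 0.19.

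Secondary wall genes had 0 of 15 members higher and 4 lower (0 and 9 adjusted over the list alone), with cellulose synthase CesA-2 (Os01g0750300) at -2.05 ± 0.54 and fasciclin-domain protein Os03g0788600 at -1.08 ± 0.23. CesA-2 was not past the test with offset 0 (adjusted p = 0.0732), the scanner software's ratios (0.119), the series table (0.119), scale normalization (0.0571) or robust eBayes (0.0658). It was not without replicate 1 or 2 (0.139 or 0.104), N2-flushed long replicate 1 (0.058) or stagnant short replicate 1, 2 or 3 (0.0712, 0.106 or 0.208). The fasciclin-domain protein stood at -0.56 with adjusted p = 0.305 under median centring. It lost its call also without replicate 1 or 3 (0.0940 or 0.0644) and without stagnant short replicate 2 or 3 (0.0557 or 0.103). The list's median was -0.85, and the list was called lower, with adjusted p = 0.00135 and adjusted p = 0.369 with an estimated correlation. Beside this group, stele and vascular markers had 0 of 5 members higher and 1 lower (0 and 1 adjusted over the list alone) and a median of 0.01. Cortex markers had 0 of 2 members higher and 0 lower (0 and 1 adjusted over the list alone) and a median of -0.63, with -0.93, -1.06 and 0.11 in the replicates. Green tissue markers had 6 of 30 members higher and 2 lower (6 and 4 adjusted over the list alone). Aquaporins, which conduct water, had 0 of 8 members higher and 3 lower (1 and 5 adjusted over the list alone), with Os07g0448800 at -1.26 ± 0.14 and NOD26-like Os02g0745100, a silicon channel, not past the test at -1.62 ± 0.56. Under median centring Os07g0448800 stood at -0.53 with adjusted p = 0.497. The aquaporin list was called lower, with adjusted p = 0.0388 and adjusted p = 0.523 with an estimated correlation. The adjusted p was 0.393 without replicate 1, 0.0526 without aerated long replicate 1 and 0.31 without stagnant short replicate 1. Laccases had 1 of 5 members higher and 2 lower (1 and 3 adjusted over the list alone) and class III peroxidases 8 of 49 members higher and 10 lower (10 and 14 adjusted over the list alone). ABCG transporters had 1 of 5 members higher and 1 lower (1 and 1 adjusted over the list alone), and expansins and xyloglucan endotransglucosylases 1 of 14 members higher and 0 lower (1 and 0 adjusted over the list alone). The wall-associated kinase Os04g0365100 was not past the test at -0.18 ± 0.10.

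Glycolysis had 1 of 48 members higher and 17 lower (2 and 19 adjusted over the list alone), with enolase Os03g0248600 at -0.73 ± 0.07 and cytosolic phosphoglycerate kinase Os02g0169300 at -0.81 ± 0.09. Under median centring they stood at -0.23 and -0.12, with adjusted p = 0.635 and 0.884. The list was called lower, with adjusted p = 1.58e-07 and adjusted p = 0.0422 with an estimated correlation. Fermentation genes had 0 of 24 members higher and 4 lower (0 and 6 adjusted over the list alone), with alanine aminotransferase Os10g0390500 at -1.73 ± 0.20, sucrose synthase 2 (Os03g0401300) at -2.05 ± 0.43, and alcohol dehydrogenases 1 (Os11g0210300) and 2 (Os11g0210500) not past the test at -0.49 ± 0.15 and 0.31 ± 0.14. Under median centring the aminotransferase and sucrose synthase stood at -1.15 and -1.29 with adjusted p = 0.132 and 0.175, and with scale normalization adjusted p was 0.082 and 0.0874. Sucrose synthase lost its call also without replicate 1 (0.123) and without stagnant short replicate 1 or 3 (0.0539 or 0.103). The fermentation median of -0.12 became 0.07 under median centring, and the list was called lower, with adjusted p = 0.00312 and adjusted p = 0.259 with an estimated correlation. Nitrogen uptake and assimilation had 1 of 34 members higher and 7 lower (1 and 7 adjusted over the list alone), with ammonium transporter Os02g0620600 at -1.40 ± 0.20. Under median centring the transporter stood at -0.75 with adjusted p = 0.347, and the list's median turned from -0.03 to 0.21. The transporter lost its call also with scale normalization (adjusted p = 0.177) and without replicate 1 (adjusted p = 0.0597). Cytosolic ribosomal proteins had 79 of 228 members higher and 0 lower (98 and 1 adjusted over the list alone) and a median of 0.16, and were called higher, with adjusted p = 4.94e-14 and adjusted p = 0.369 with an estimated correlation. MYB factors had 13 of 94 members higher and 1 lower (13 and 1 adjusted over the list alone), including Atmyb5-like Os01g0975300 at 1.67 ± 0.19, and NAC factors had 6 of 32 members higher and 4 lower (7 and 5 adjusted over the list alone). AP2/ERF factors had 5 of 29 members higher and 3 lower (6 and 5 adjusted over the list alone), WRKY factors 3 of 45 members higher and 3 lower (4 and 5 adjusted over the list alone) and ethylene genes 1 of 19 members higher and 1 lower (1 and 1 adjusted over the list alone). Heat shock proteins had 10 of 92 members higher and 1 lower (10 and 1 adjusted over the list alone), including heat shock protein 82 (Os09g0482100) at 0.86 ± 0.10, or 1.54 with adjusted p = 0.0969 under median centring, and cell division genes had 8 of 87 members higher and 7 lower (11 and 8 adjusted over the list alone). The medians of peroxidases, ethylene genes, the wall-associated kinase, expansins, heat shock proteins, cell division genes and stele genes also turned their sign under at least 1 scaling. Median, mean and test differed in sign for ethylene genes, AP2/ERF and WRKY factors, heat shock proteins, stele genes and green tissue genes, and no such list was called.

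Against stagnant short roots, 2059 loci passed the limma test, 1151 higher and 908 lower, and 200 of them differed at least 2-fold. The count was 737 with median centring, 70.7% of them higher in place of 55.9%, 1357 with scale normalization and 614 on the comparison's own replicates, 632, 442 or 680 without replicate 1, 2 or 3 of every comparison, and 1345, 879 or 919 without stagnant short replicate 1, 2 or 3 alone. Among genes named against stagnant short roots, the calls lost (adjusted p in parentheses) were 3 with the scanner software's ratios (0.0913 to 0.119), 2 with robust eBayes (0.057 to 0.0658), 12 with median centring (0.0797 to 0.884), 3 with offset 0 (0.0566 to 0.0732), 17 with scale normalization (0.0555 to 0.177), 3 with the series table (0.0913 to 0.119), 1 without N2-flushed long replicate 1 (0.058), 9 without replicate 1 (0.0565 to 0.148), 7 without replicate 2 (0.0586 to 0.104), 2 without replicate 3 (0.0605 to 0.0644), 3 without stagnant short replicate 1 (0.0539 to 0.0756), 4 without stagnant short replicate 2 (0.0557 to 0.106) and 5 without stagnant short replicate 3 (0.103 to 0.208).

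**Figure D3:**
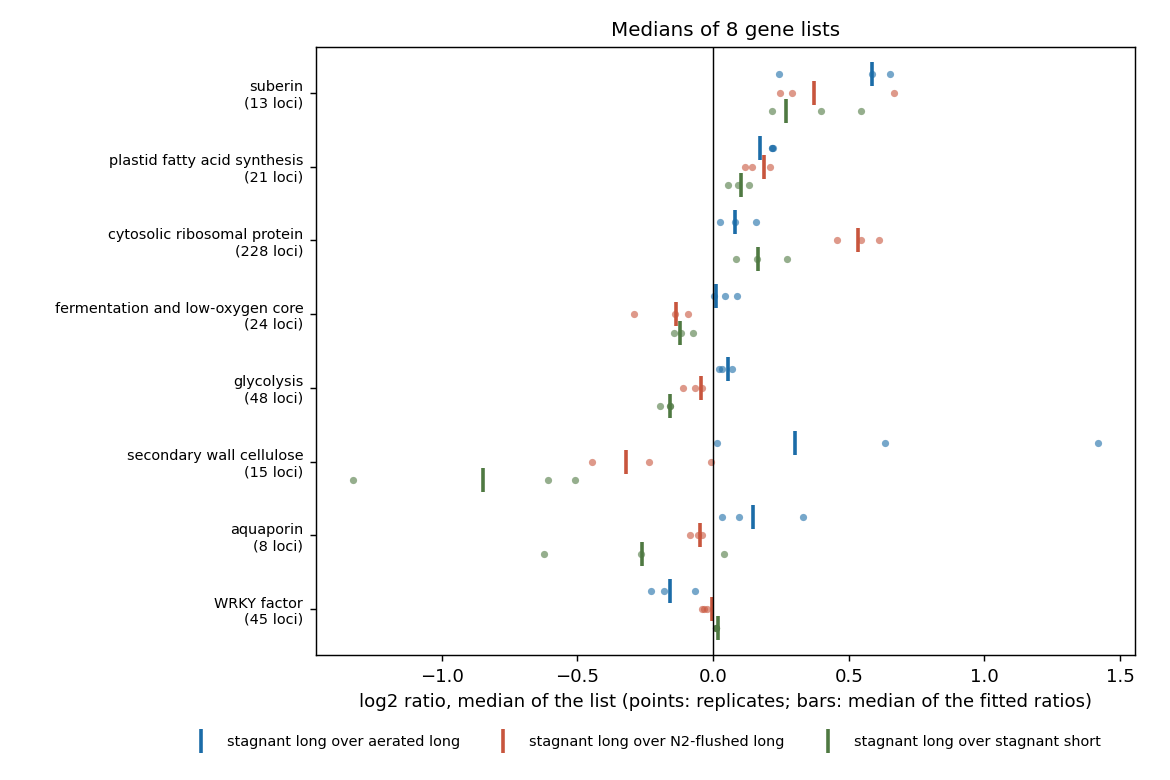
Median log2 ratio (x axis) of 8 gene lists (y axis), with points for the 3 replicates and bars for the median of the fitted ratios, in 1 colour per comparison. Secondary wall genes lay at -0.85 against stagnant short roots and cytosolic ribosomal proteins at 0.53 against N2-flushed roots, while under median centring WRKY factors turned from -0.16 to 0.19 against aerated roots, and fermentation from -0.12 to 0.07 and glycolysis from -0.16 to 0.12 against stagnant short roots.

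Genes that changed the same way in all 3 comparisons set stagnant long roots apart from each other kind of root. By the largest of the 3 p values, adjusted over loci, there were 20, 13 higher and 7 lower. Of these, 10 changed at least 2-fold in each comparison. Sizes here are the smallest of the 3 log2 changes. PspC gene Os07g0599700 (2.31) and Os07g0599900 (2.14), close to it by locus number and of no described function, led the higher ones. Genes whose descriptions name acyl lipids were acyltransferase Os05g0457800 (1.60), acyl-CoA-binding protein Os06g0115300 (0.92) and acyl-ACP thioesterase Os06g0596300 (0.66), which releases fatty acids from the plastid pathway. ABC transporter Os01g0836600 (1.04), alpha/beta hydrolase Os01g0317800 (0.99), unknowns Os05g0245300 (1.37), Os06g0538900 (1.05) and Os01g0886900 (0.67), and Os01g0253800 (1.33), which has no description, were also higher. So was multicopper oxidase Os01g0127000, whose signal was well above background on 0 of 6 arrays in each of the other RNAs. Its mean level was at least 1.55-fold, 1.62-fold and 1.64-fold higher than in aerated, N2-flushed and stagnant short roots. The lower ones included asparagine synthetase (Os03g0291500, 2.33), the CI2C gene Os12g0548700 (2.31), cysteine protease ervatamin B (Os01g0347600, 1.37), allantoin permease Os12g0503000 (1.00), which moves a nitrogen-rich compound, short-chain dehydrogenase Os12g0260500 (0.76) and Os03g0744600 (0.62). Adjusted p lay between 0.000807 and 0.0486 for these genes in limma with the largest of the 3 p values. Leaving out replicate 1, 2 or 3 of every comparison gave 0, 0 or 2 loci in limma, with 559, 409 or 441 at an unadjusted p under 0.05. Leaving out a replicate of 1 group gave 4 or 8 (aerated long 2 or 3), 5 (N2-flushed long 1) and 2, 2 or 9 (stagnant short 1, 2 or 3), against 14 to 26 for each of the others. The count was 0 with scale normalization and on each comparison's own replicates (496 and 572 at an unadjusted p under 0.05), and between 11 and 157 under the other settings. Of the 98 loci with median centring, 8 were among the 20.

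The overlap of the comparisons asks whether the same loci move. By the adjusted p of each comparison, 169 loci were past the test and higher in each, 108 were lower in each, and 1744 moved the same way in at least 2 of the 3. This rule is looser than adjusting the largest of the 3 p values, which gave 20 loci. Against aerated and N2-flushed roots, 473 loci were higher in both and 591 lower in both, where independent draws give 154 and 185, and 201 moved in opposite directions. Against aerated and stagnant short roots the counts were 284 and 205, where independent draws give 107 and 90.8, with 206 opposite. Against N2-flushed and stagnant short roots they were 440 and 305, where independent draws give 119 and 104, with 156 opposite. The stagnant long RNA stands in all 3 comparisons, so part of the excess may come from shared controls. In 20 simulations of unchanged groups with the replicate correlation of 0.22, correlations between comparisons were 0.22, 0.22 and 0.22 across loci, against 0.44, 0.16 and 0.41 observed. The simulated correlations return the value that was put in. Deviations of same-numbered ratios correlated with a median of 0.399 across loci, so the simulated comparisons may share too little. The difference in correlation is therefore no measure of an excess. Genes are not independent replicates. The simulations put 0 loci past the test in both, and 84.2%, 83.5% and 84.7% of loci under an unadjusted p of 0.05 in both had 1 sign, against 84.1%, 70.4% and 82.7% of the observed loci past the test. The covariance was 0.0515, 0.0159 and 0.0409, with 0.00231, 0.00229 and 0.00234 simulated. Between ratios of different replicate numbers, which share no array pair, it was 0.0448, 0.00955 and 0.0371. Correlations of such ratios ran from 0.289 to 0.343 for aerated and N2-flushed and from 0.141 to 0.364 for N2-flushed and stagnant short roots. For aerated and stagnant short roots they ran from -0.144 to 0.317, so the sign differed between replicates.

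N2-flushed and aerated long roots were compared through their common stagnant partner, with no array that held both. In N2-flushed roots 848 loci were higher and 839 lower than in aerated roots, 1687 in all, and 310 differed at least 2-fold. GDSL lipase Os01g0216000 at 5.01 ± 0.54 (adjusted p = 0.00132), metallothioneins Os12g0571000 at 4.63 ± 0.23 and Os12g0568200 at 3.62 ± 0.54, haemoglobin 1 (Os03g0233900) at 3.90 ± 0.53 and B12D protein Os07g0604600 at 3.15 ± 0.49 were higher past the test. The aerated signal of the last was well above background on 1 of 6 arrays, so the size of its difference is uncertain. Eggshell-family protein Os10g0452400 at -3.80 ± 0.26, anionic peroxidase Os04g0688100 at -3.13 ± 0.24, peroxidase 1 (Os05g0162000) at -3.09 ± 0.23 and acidic chitinase Os01g0660200 at -2.85 ± 0.50 were lower. Protein kinase Os11g0691600 was lower as well (adjusted p = 0.00131), but its N2-flushed signal was well above background on 0 of 6 arrays, so no size is given. Under median centring Os04g0688100, Os05g0162000 and Os01g0660200 stood at -1.98, -2.19 and -1.96, with adjusted p = 0.16, 0.0959 and 0.166. Cytosolic ribosomal proteins had 1 of 228 members higher and 121 lower (3 and 154 adjusted over the list alone), and glycolysis had 17 of 48 higher and 0 lower (18 and 2 adjusted over the list alone). The count was 454 with median centring, 75.8% of them higher in place of 50.3%, and 2652 with a replicate block. Leaving out replicates 1, 2 or 3 gave 887, 43 or 610. Leaving out aerated long replicate 2 or 3 gave 990 or 968, and N2-flushed long replicate 2 or 3 gave 708 or 970. Of the 10 genes named, the calls lost (adjusted p in parentheses) were 3 with median centring (0.0959 to 0.166), 1 with scale normalization (0.0571), 5 without replicate 2 (0.0718 to 0.127) and 1 without replicate 3 (0.0717).

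Stagnant short and aerated long roots, compared in the same indirect way, differ in both solution and length. In stagnant short roots 981 loci were higher and 1204 lower, 2185 in all, and 508 differed at least 2-fold. Nicotianamine synthase 1 (Os03g0307200) at 3.72 ± 0.41 (adjusted p = 0.00113), haemoglobins 1 (Os03g0233900) at 3.70 ± 0.53 and 2 (Os03g0226200) at 3.01 ± 0.42, GDSL lipase Os01g0216000 at 3.25 ± 0.54 and fasciclin-domain protein Os05g0563600 at 2.96 ± 0.57 were higher past the test. Beta-glucanase Os05g0375400 at -3.55 ± 0.60, germin-like protein 6 (Os08g0189600) at -3.30 ± 0.34, F-box protein Os02g0671100 at -3.18 ± 0.37, CTP synthase (Os01g0654100) at -3.16 ± 0.22 and eggshell-family protein Os10g0452400 at -3.04 ± 0.26 were lower. The stagnant short signal of the F-box protein was well above background on 2 of 6 arrays, so the size of its difference is uncertain. Secondary wall genes had 7 of 15 members higher and 0 lower (10 and 1 adjusted over the list alone), with a median of 1.68. Beside them, the medians of cortex, stele and green tissue markers were 0.91, 0.07 and -0.08, with 0 of 2 cortex markers higher (1 adjusted over the list alone). The count was 468 with median centring, 62.4% of them higher in place of 44.9%, 1228 with scale normalization and 3323 with a replicate block. Leaving out replicates 1, 2 or 3 gave 1168, 207 or 843. Leaving out aerated long replicate 2 gave 960, and stagnant short replicate 2 or 3 gave 1210 or 1222. Of these 10 named genes, the calls lost (adjusted p in parentheses) were 2 with scale normalization (0.0529 to 0.228), 1 without replicate 1 (0.0799), 5 without replicate 2 (0.0504 to 0.0962) and 1 without replicate 3 (0.0595).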

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

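Signal appeared on probes for microRNAs, which no comparison of gene loci used. Of 510 microRNA probes, 18 were well above background in stagnant long RNA on at least 14 of 18 arrays, and 0 of 24 probes of random or artificial sequence were. These controls are too few to set the microRNA probes apart from them. In limma, 3 of these 18 passed an adjusted p of 0.05 in a comparison. The microRNA probes were not among the 16094 loci, so their p values were not adjusted together with those of loci. The adjusted values of probes and loci are therefore not comparable. The 3′ probe for miR156d stood at -0.23 against aerated long roots, with adjusted p = 0.0149. The 5′ probe for miR419 stood at -0.85 against aerated long roots and at -1.10 against N2-flushed long roots, with adjusted p = 0.0149 and 0.00755. The mature-sequence probe for miR529 stood at -0.32 and -0.28 in the same comparisons, with adjusted p = 0.0149 and 0.0204. No explanation was tested.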

How the results depend on the processing

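Of 386 values of the main results under alternatives, 287 kept their direction and their side of the threshold or stayed within 1.5 times, and of 4593 values of single genes and other lists 4327 did, where a list's direction is that of its test against other genes. Among the latter 203 were no longer past the threshold and 60 came past it. Many alternatives could hardly move a value, so these shares overstate stability. Leaving out a replicate of 1 group leaves the ratios of the other direct comparisons unchanged, and only their test can change. The series table correlated at 0.999999 with the scanner software's ratios on each array, so these settings are nearly the same. The sign of 3 single genes turned, against aerated long roots under median centring: phenylalanine ammonia-lyase Os02g0627100 to 0.14, enolase Os10g0167300 to 0.35 and NAC gene Os01g0261200 to 0.27. The median of all loci stood at 0.29 there. Under the same scaling the medians of 3 called lists turned while their tests kept direction: WRKY factors against aerated roots to 0.19, and fermentation and glycolysis against stagnant short roots to 0.07 and 0.12. Except where a reason is given, the cause was not tested.

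Counts at least 2-fold against aerated, N2-flushed and stagnant short roots were 1678, 1369 and 899 with the scanner software's ratios, 1677, 1367 and 898 with the series table, 1008, 685 and 494 with offset 0, and 198, 558 and 126 with scale normalization. Median centring gave 855 against aerated roots. Median centring gave 887 loci past the test against N2-flushed roots and 737 against stagnant short roots, 70.7% of them higher in place of 55.9%. It gave 454 and 468 loci in the indirect comparisons of N2-flushed and stagnant short with aerated roots, 75.8% and 62.4% higher in place of 50.3% and 44.9%, and 637 loci the same way in at least 2 comparisons. Scale normalization gave 1755 against aerated roots, 1357 against stagnant short roots and 1228 in the indirect comparison of stagnant short roots. Fits on a comparison's own replicates gave 1522 against aerated and 614 against stagnant short roots and 900 in the overlap. These fits have fewer degrees of freedom, and they do not share the spread of the other comparisons. Ratios of replicates correlated between 0.52 and 0.73 within stagnant short, 0.66 and 0.72 within aerated and 0.74 and 0.83 within N2-flushed comparisons. Which of these lowered the counts was not tested.

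The pairing by number was fitted as a replicate block, which gave 2652 and 3323 loci in the indirect comparisons as a random block and 2648 and 3366 as a fixed block. The random block also brought the suberin list against N2-flushed roots, median 0.37, past the test, and moved no other count by over 1.5 times. Loci changed in all 3 comparisons numbered 53 with the scanner software's ratios and with the series table, 59 with offset 0, 31 without background subtraction, 98 with median centring, 157 with both arrays of a swap, 46 with separate channels, 13 with robust eBayes and 11 with the mean over probes. Limma gave 0 with scale normalization and on own replicates, where 496 and 572 loci had an unadjusted p under 0.05. List calls numbered 19 on own replicates and with separate channels, 22 with both arrays of a swap, 27 by fry and 1 with an estimated correlation. The suberin median against aerated roots, 0.59, came past the test with no filter, on own replicates, with both arrays and by fry. Against N2-flushed roots it did so at 0.46 with median centring and at 0.37 on own replicates, with both arrays, with separate channels and by fry. Against stagnant short roots, at 0.27, it was no longer past the test with an estimated correlation, though that estimate, 0.0044, lay below the preset of 0.01.

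Leaving out replicates gave 555 to 3175 loci against aerated roots, 912 to 3608 against N2-flushed roots and 442 to 1968 against stagnant short roots, and 201 to 422, 251 to 378 and 132 to 215 at least 2-fold. The indirect comparisons gave 43 to 1753 and 207 to 2127, the loci changed in all 3 comparisons 0 to 26, and the overlap 307 to 1560. List calls numbered 11 to 16. The suberin median ran from 0.45 to 0.62 against aerated roots, from 0.37 to 0.46 against N2-flushed roots, where it came past the test at 0.40 without replicate 3, and from 0.27 to 0.32 against stagnant short roots. Without replicate 2 most counts were lowest, and fewer replicates leave fewer degrees of freedom. A separate block for slides was not run, since slides coincide with replicate numbers once the dyes are averaged. On all 6 slides the aerated long array stood at position 1, stagnant short at 3 and N2-flushed long at 4. Position on the slide therefore cannot be told apart from the comparison, which bears also on the indirect comparisons. Signal over background limits genes such as acyl-ACP desaturase Os01g0880800, whose aerated signal was well above background on 0 of 6 arrays.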

Other observations

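The lists in the first 2 paragraphs, the test of ribosomal genes in N2-flushed against aerated roots and both tests on secondary wall genes were chosen after results had been seen, so neither the counts nor the p values of those lists are independent evidence. Against aerated long roots, germin-like proteins, many of which make hydrogen peroxide in the wall, had 0 of 15 members higher and 12 lower (0 and 13 adjusted over the list alone), with adjusted p = 1.03e-12 and adjusted p = 0.0924 with an estimated correlation. Chitinases had 2 of 22 members higher and 10 lower (3 and 13 adjusted over the list alone), with adjusted p = 1.34e-05 and adjusted p = 0.0747 with an estimated correlation. Proteinase inhibitors had 1 of 23 members higher and 12 lower (1 and 13 adjusted over the list alone), with adjusted p = 5.10e-05 and adjusted p = 0.159 with an estimated correlation. Against N2-flushed roots the inhibitors had 0 of 23 members higher and 8 lower (0 and 8 adjusted over the list alone), with adjusted p = 0.0119 and adjusted p = 0.459 with an estimated correlation. The median of chitinases against stagnant short roots turned from -0.13 to 0.14 under median centring.

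Iron acquisition genes had 0 of 9 members higher and 7 lower (0 and 7 adjusted over the list alone) against stagnant short roots, with adjusted p = 0.000287 and adjusted p = 0.0926 with an estimated correlation, and against aerated roots 4 of 9 members higher and 0 lower (4 and 0 adjusted over the list alone). Metallothioneins had 3 of 13 members higher and 1 lower (6 and 1 adjusted over the list alone) against aerated roots, with adjusted p = 0.0243 and adjusted p = 0.418 with an estimated correlation. Proteasome subunits, which degrade proteins, had 22 of 54 members higher and 1 lower (25 and 1 adjusted over the list alone) against N2-flushed roots, with adjusted p = 7.18e-08 and adjusted p = 0.459 with an estimated correlation. Tubulins and actins, the cytoskeleton, had 11 of 31 members higher and 0 lower (12 and 0 adjusted over the list alone) against aerated roots, with adjusted p = 9.60e-05 and adjusted p = 0.264 with an estimated correlation, and were called against N2-flushed roots with adjusted p = 0.0314 and adjusted p = 0.459 with an estimated correlation. Mitochondrial and plastid ribosomal proteins had 8 of 42 members higher and 0 lower (8 and 0 adjusted over the list alone) against stagnant short roots, with adjusted p = 0.0327 and adjusted p = 0.701 with an estimated correlation. Lipases and hydrolases had 13 of 66 members higher and 6 lower (16 and 7 adjusted over the list alone) against aerated roots and glutathione S-transferases 4 of 30 members higher and 7 lower (8 and 11 adjusted over the list alone), and camera called neither list in a comparison. Fry called lipases and hydrolases higher in all 3 comparisons, with adjusted p = 0.0264, 0.0259 and 0.0189, and glutathione S-transferases against N2-flushed roots, with adjusted p = 0.0439. The glutathione S-transferase median against aerated roots turned from -0.04 to 0.51 under median centring. Medians near 0 also turned under at least 1 scaling for metallothioneins and glutathione S-transferases against N2-flushed roots, and for germin-like proteins, proteinase inhibitors and the proteasome against stagnant short roots.

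Cytosolic ribosomal protein genes had a median of 0.53 against N2-flushed long roots. The highest median of 10000 random lists of like brightness was 0.0599, so other genes as bright did not share the shift. Loess sets the ratios of most genes near 0 at each brightness, so such lists stay near 0 in any case. They cannot decide whether normalization contributed. A single slide or dye is argued against, since the lowest of the 6 array medians was 0.405. All 6 arrays stood at position 4 of their slides, so an effect of position stays open. A candidate explanation is a lower level under N2 flushing than in aerated roots, where the indirect median was -0.448 and the lowest random list -0.0782. That indirect value is built from the direct ratios against aerated and N2-flushed roots, whose list medians were 0.08 and 0.53. It is no separate measurement and holds the same N2-flushed RNA, so a property of those samples other than the treatment stays open.

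Secondary wall genes had a median of -0.85 against stagnant short roots. Vascular tissue dissected with the outer cells could contribute. It cannot be told apart from a change in the outer cells, since 1 gene of the vascular list was well above background on all 6 arrays in both RNAs, and the list's median was 0.0068. Cortex markers, 2 genes, had a median of -0.63, and admixed cortex was not tested. By the labels, stagnant long and stagnant short roots share solution, position and time, and differ in length. Whether length alone lowers these genes was not decided. The median against N2-flushed long roots was -0.320, with replicate medians of -0.23, -0.01 and -0.45. Those roots are of like length and differ in solution, so this value cannot bear on length.

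Neighbouring loci moved together against N2-flushed long roots, the comparison in which this was tested. Of 16082 neighbouring pairs, 23 were past the test and at least 2-fold the same way. The 10000 shuffles gave at most 13 and on average 3.74. Co-regulation of neighbours could give such an excess. Of the 23 pairs, 8 had the same description and 15 different ones, which alone exceeds 13. Some of the 15 still name like proteins, as wound-induced inhibitors Os01g0131900 and Os01g0132000 do. Some loci stand in more than 1 pair, and shuffles scatter like neighbours, so the excess cannot single out co-regulation. Probes that bind each other's transcripts could do the same, and 8.70% of the pairs, 2 of 23, had probes that share 15 bases. The limit of 10% set beforehand was met by that share but not by its upper 95% limit of 28.0%, and this requirement was added after the share was seen. Probes in different parts of 2 like transcripts need share no bases, so this stays open.

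With 3 replicates the splits are too few for a share under 0.05. Of 4 ways to set the signs of replicates, 1, the real one, gave as many loci in each direct comparison. The real counts were 3106, 3508 and 2059, and the highest other was 0 in each by limma, with 855, 411 and 832 at an unadjusted p under 0.05. For loci changed in all 3 comparisons the real count was 20 and the highest other 0, with 3 at an unadjusted p under 0.05. Of 10 splits, 1, the real one, gave as many loci in each indirect comparison. The real counts were 1687 and 2185 and the highest other 0, with 1053 and 1339 at an unadjusted p under 0.05.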
